A study of Mus musculus with 3 samples.

How the data were processed

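Total RNA of thymocytes from 3 wild-type mice was extracted with Trizol, labelled with biotin and hybridised to Affymetrix MoGene 1.0 ST arrays, per the labels' protocols. The labels name 1 group with 3 mice, and the lymphoma arrays of the study were not used here. The deposited table holds log2 levels for 35557 probe sets and 3 arrays, with values from 1.76 to 14.96; the log2 scale was inferred from this range. Affymetrix Expression Console produced the values, per the submitters' processing notes, and its version, the background correction, the summarisation and the normalisation between arrays are not given in the sources used here. The authors' normalisation may have used arrays that were not analysed here. Nothing in the labels gives scan dates. The labels number the mice but do not otherwise describe how the samples were taken, so the limma p-values measure the spread between these 3 samples. Fisher's exact tests and the permutation tests set genes against genes, and their p-values measure no spread between mice.

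Probe sets were named from the platform annotation. Of the 35557 probe sets, 21789 had a single gene symbol, 1621 had several and were not named, and 12147 were not listed in the annotation and stay unnamed. The single symbols covered 19938 genes; probe sets of the same gene (999 genes had more than 1) were averaged. Of the named probe sets, 21698 had an Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be updated. No genome build is given for the array's probes, so no coordinates are printed and the table served only for names and gene order. Of the 413 symbols on the fixed lists, 362 had a probe set of their own. The other symbols are not reported here.

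Background was taken from 1208 olfactory, vomeronasal and trace amine receptor genes, which are transcribed in the nasal epithelium. A gene was above background when it exceeded the 95th percentile of these genes on each of the 3 arrays. The thresholds lay between 5.91 and 6.10, and 12314 genes, 61.8%, passed. The receptor median was 4.00, 4.17 and 4.05, so these receptor genes read lowest on the array of mouse 92.

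Gene lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those identified below as added. The share of list members above background was compared with all other named genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 25 lists, and the medians of random lists were computed but are not reported, because probes differ in affinity. The highest levels of a list served only to choose examples. The sex-linked list was reported gene by gene. Variation between mice was tested with limma 3.58.1 in R 4.3.3: an intercept was fitted, eBayes gave a robust prior variance with a trend on level, and each gene's variance over its prior was tested as an upper-tail F ratio, with 13.4 prior degrees of freedom estimated from the bulk of genes. The plan did not say which degrees of freedom a robust prior contributes, and this choice was made after the data were examined. The test was run at first with the per-gene degrees of freedom that the robust prior gives, which are smaller for genes that stand out, and limma then called 0 genes, with 600 at an unadjusted p under 0.05. The degrees of freedom of the bulk of genes were used instead, because the per-gene ones are reduced by the same kind of outlier test, and the count of varying genes depends on this change. On simulated data with the levels and prior of the 13316 tested genes, the test recovered 50 of 100 genes shifted by 1 in 1 mouse and 100 of 100 shifted by 2 on the log2 scale, with 3 false calls, and made 0 calls when nothing was shifted. With the per-gene degrees of freedom it recovered 0 of the genes shifted by either amount. The simulated variances were drawn from the same prior that the test assumes, and the simulated genes were independent. Few false calls were therefore built in, and they do not show that the chosen degrees of freedom hold for the real data.

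For shared variation, the deviations of a list's members from their 3-mouse means were averaged per mouse, and the SD of these 3 averages was set against 10000 random lists drawn from the same 20 level bins. Random lists do not carry the co-regulation of real gene groups, so percentiles describe these arrays and no p-value is given. In simulated data a neutrophil list shifted by 0.5 in 1 mouse stood at the 100th percentile, and 0 of 24 unshifted lists reached the 99th. The simulated genes were independent and shared a common SD, so few unshifted lists at the 99th percentile were built in. The simulation does not show how often lists of co-regulated genes reach that percentile in real data.

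The genes named were the 3 with the highest mean level of each list among those above background on all arrays, the members of 3 core lists not above background (0 were found), the 20 genes with the smallest adjusted p for variation, and the sex-linked genes. Genes named as passing when adjusted over a list alone, or because a count was small, were chosen after their values were seen. Alternatives were quantile normalisation, centring on the median, leaving out each mouse, single probe sets, other background thresholds, other priors and other filters. Cyclic loess normalisation, the per-gene prior degrees of freedom, leaving out the sex-linked list and leaving the receptor genes out of the comparison set were added after seeing the data. A background from antigenomic control probes was not run, because no annotation used here names them. Figures were drawn with matplotlib 3.10.9.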

Results

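The transcriptome of thymocytes, the developing T cells of the thymus, was measured in 3 wild-type mice on Affymetrix mouse gene arrays, which read each transcript with a set of short probes. The mice, numbered 92, 103 and 106 in the labels, had a mixed FVB and C57BL6 background. They form the normal group of a study of invasive lymphomas in mice; the lymphomas were not analysed here, so that no tumour-to-normal comparison was made. The labels record 0.3 µg of RNA and an RNA integrity number of 3 for each sample. They also carry a lymphoma entry under disease state for these 3 samples, although the titles and genotypes read wild type. Each array gave a level for 35557 probe sets, with medians of 6.70, 6.71 and 6.72 on the log2 scale for mice 92, 103 and 106. The number of arrays, 3, limits the precision of every value. The RNA integrity number is low and, if the label holds, RNA degradation may limit every value too. No label gives the sex or age of the mice.

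The arrays of mice 103 and 106 resembled each other more closely than either resembled that of mouse 92. Across 19938 named genes, Pearson's r was 0.994 for mice 103 and 106, 0.993 for mice 92 and 106 and 0.992 for mice 92 and 103, with Spearman's rho at 0.994, 0.993 and 0.992. These are correlations across genes, which are not independent replicates. The number of genes that differed by at least 1 on the log2 scale was 25, 57 and 91 in the same order. The SD over genes of the pairwise difference was 0.23, 0.26 and 0.29. Among genes above background on all 3 arrays these numbers were 14, 34 and 44.

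The question of which programmes were transcribed in normal thymocytes was addressed with gene lists fixed before the data were examined. Every measured gene of the T cell receptor and early signalling list, 18 of 18, lay above background on all 3 arrays. Cd3g, a chain of the CD3 complex, had a level of 13.30 ± 0.04 (SD, n = 3) on the log2 scale. The signalling adaptor gene Lat had a level of 12.80 ± 0.07, and Ptprc, which encodes CD45, a level of 12.55 ± 0.20 (SD, n = 3). All 18 measured genes of the double-positive thymocyte list were also above background. Among them, the chromatin organiser Satb1 had a level of 13.70 ± 0.07, the recombinase gene Rag1 13.59 ± 0.22 and the co-receptor gene Cd8a 13.21 ± 0.03 (SD, n = 3). The list of maturing single-positive T cells had 19 of 19 genes above background, including Gimap6 at 11.42 ± 0.22, Gimap4 at 11.21 ± 0.20 and Slfn2 at 10.47 ± 0.09 (SD, n = 3). In the list of early progenitors and double-negative cells, 15 of 18 genes were above background. Its examples were Notch1, the receptor that drives T cell commitment, at 10.57 ± 0.32, the IL-7 receptor gene Il7r at 10.39 ± 0.22 and the Notch target Dtx1 at 8.88 ± 0.54 (SD, n = 3).

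Genes of proliferation, growth signalling and metabolism were above background throughout their lists. All 23 cell cycle and DNA replication genes passed, with the sliding clamp gene Pcna at 12.28 ± 0.16, the ribonucleotide reductase gene Rrm1 at 11.20 ± 0.06 and the proliferation marker Mki67 at 11.10 ± 0.26 (SD, n = 3). All 22 measured PI3K-AKT-mTOR genes passed, including Akt2 at 10.87 ± 0.04, Pdpk1 at 10.70 ± 0.15 and the catalytic subunit gene Pik3ca at 10.68 ± 0.19 (SD, n = 3). All 13 glycolysis genes passed (Ldha 12.21 ± 0.09, Pgk1 11.32 ± 0.19, Hk1 11.19 ± 0.07, log2 level ± SD, n = 3). All 13 BCL2 family genes passed (the survival genes Mcl1 at 12.53 ± 0.14 and Bcl2l1 at 10.97 ± 0.14, the death-promoting Bcl2l11 at 9.63 ± 0.24, log2 level ± SD, n = 3). The list named T cell leukaemia and lymphoma oncogenes had 18 of 22 genes above background, with Ccnd3 at 12.08 ± 0.25, Ikzf1 at 11.58 ± 0.12 and Cdk4 at 11.49 ± 0.13 (SD, n = 3). Despite its name, this oncogene list also holds tumour suppressor genes, among them Ikzf1, Fbxw7, Cdkn1b, Cdkn2a and Cdkn2b. The 12 housekeeping genes all passed, with Actb at 14.18 ± 0.02, Eef1a1 at 14.17 ± 0.06 and Rplp0 at 13.38 ± 0.11 (SD, n = 3).

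Immediate early and heat shock genes passed in 17 of 19 cases (Hspa8 13.01 ± 0.17, Btg2 11.50 ± 0.09, Hsph1 10.83 ± 0.24), glucocorticoid response genes in 11 of 12 (Txnip 12.00 ± 0.09, Fkbp5 11.09 ± 0.06, Nr3c1 10.32 ± 0.11) and interferon-induced genes in 11 of 13 (Irf7 9.22 ± 0.12, Zbp1 9.10 ± 0.13, Rtp4 8.78 ± 0.29; log2 level ± SD, n = 3). All 7 measured MHC class I and related genes passed, with H2-Q2 at 12.26 ± 0.09, B2m at 12.19 ± 0.17 and H2-Q4 at 11.62 ± 0.07 (SD, n = 3).

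Some markers of other cells also read above background. B cell, erythroid and neutrophil genes passed in 64.3%, 62.5% and 58.3% of cases, near the 61.8% of other named genes. A pass therefore does not show that such cells were present. All 8 measured MHC class II genes passed (Cd74 10.12 ± 0.46, H2-Aa 9.95 ± 0.22, H2-Ab1 9.86 ± 0.30), as did 15 of 19 macrophage and dendritic cell genes (Lyz2 10.02 ± 0.66, Ctss 9.88 ± 0.22, Cd68 8.04 ± 0.28), 9 of 14 B cell genes (Ly6d 10.40 ± 0.18, Cd79b 8.96 ± 0.56, Cd79a 7.94 ± 0.72), 11 of 16 genes of gamma-delta T, NK and cytotoxic cells (Ccl5 9.28 ± 0.57, Nkg7 9.13 ± 0.42, Il2rb 8.67 ± 0.17), 7 of 12 neutrophil genes and 5 of 8 erythroid genes. Ly6d is transcribed in thymocytes as well as in B cells. Thymic epithelial genes passed in 10 of 14 cases (Cldn4 8.64 ± 0.16, Ly75 8.59 ± 0.04, Krt8 7.44 ± 0.44) and fibroblast and endothelial genes in 6 of 14 (Pecam1 9.65 ± 0.09, Col1a1 7.40 ± 0.11, Col1a2 7.13 ± 0.14; log2 level ± SD, n = 3). Adipocyte genes passed in 1 of 10 cases (Retn, 6.07 ± 0.13) and liver and brain genes in 3 of 14 (Mbp 7.88 ± 0.09, Apoa1 6.60 ± 0.16, Apoa2 6.53 ± 0.23). Skeletal muscle genes passed in 8 of 10 cases (Mylpf 7.80 ± 0.10, Tnni2 7.35 ± 0.06, Acta1 7.23 ± 0.16).

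Of the 25 lists tested, 9 had more members above background than the other named genes, of which 61.7% to 61.8% passed, depending on the list left out (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the lists). The adjusted p was 0.00144 for the T cell receptor list, 0.00144 for the double-positive list, 0.00132 for the single-positive list, 4.02e-04 for the cell cycle list, 4.02e-04 for the PI3K-AKT-mTOR list, 0.00855 for glycolysis, 0.00855 for the BCL2 family, 0.0124 for housekeeping and 0.0357 for the immediate early and heat shock list. Adipocyte genes (adjusted p = 0.00476) and liver and brain genes (adjusted p = 0.0104) passed less often than other genes in the same exact test. The other 14 lists did not pass the threshold, among them early progenitors (adjusted p = 0.135), oncogenes (0.128), MHC class II (0.0573), B cells (1) and neutrophils (0.843). Probes differ in affinity, so the levels do not show which gene or list was transcribed more than another, and genes are not independent replicates. With background at the 99th percentile of the receptor genes, the BCL2 family (adjusted p = 0.0991) and the immediate early list (adjusted p = 0.121) no longer passed Fisher's exact test, and the latter also did not with the receptor genes left out of the comparison (adjusted p = 0.0656).

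**Figure D1:**
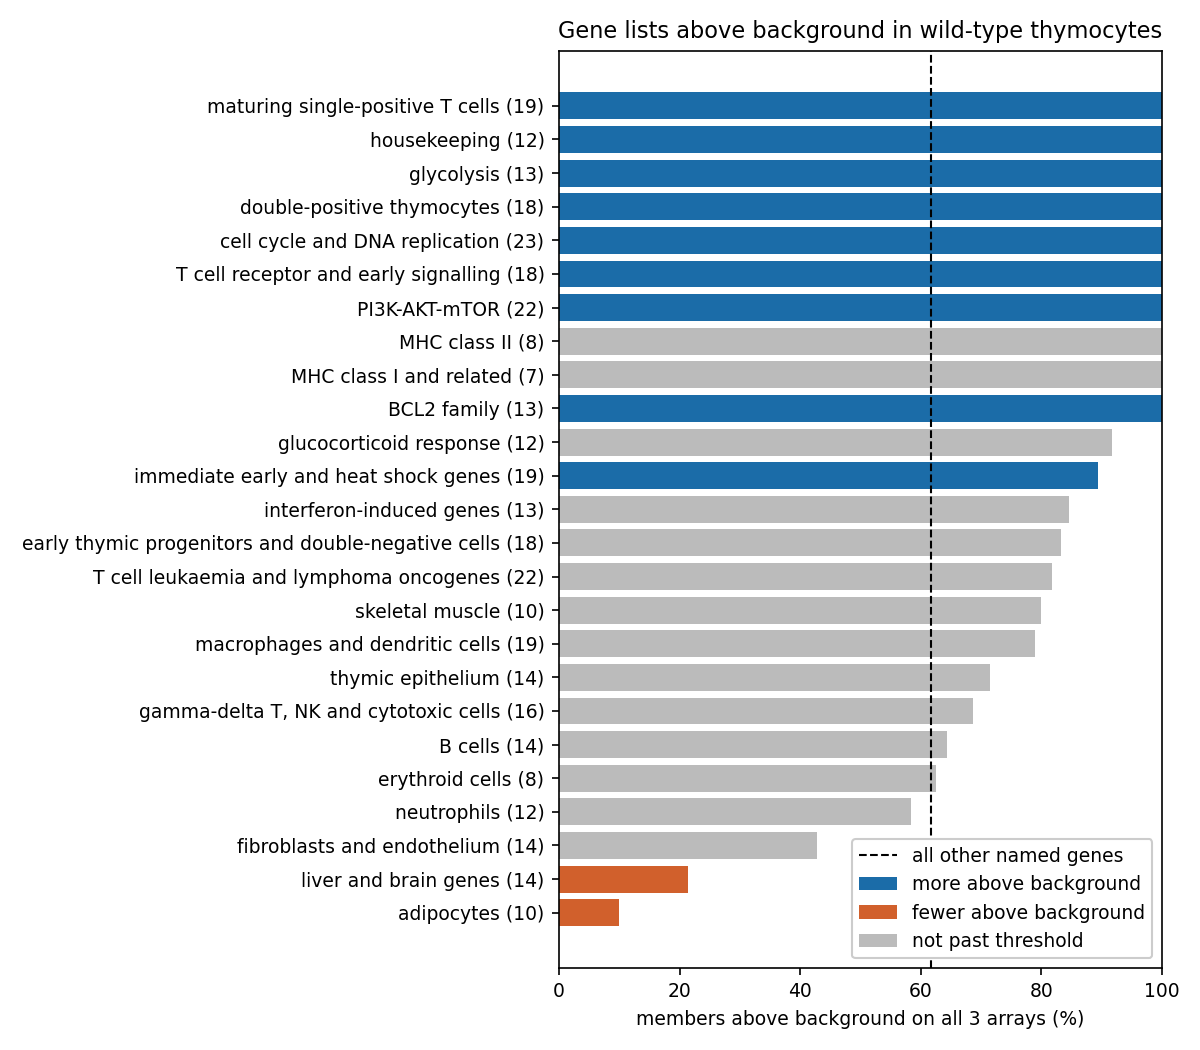
Percentage of the measured members of each gene list (number in brackets) above background on all 3 arrays of wild-type thymocytes; bars are coloured by the outcome of Fisher's exact test and the dashed line marks the other named genes, at 61.7% to 61.8%. The T cell receptor, double-positive and PI3K-AKT-mTOR lists reach 100%, the adipocyte list 10%.

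The spread between mice was asked gene by gene, without dividing the mice into groups. Of 13316 genes above background on at least 1 array, 44 varied between the mice by more than genes of like level did (limma, robust trended prior, Benjamini-Hochberg adjusted p under 0.05), and 729 had an unadjusted p under 0.05 where 665.8 were expected by chance. The 4 measured sex-linked genes had the 4 smallest p-values. Xist, the RNA that coats the inactive X chromosome (probe set 10606178), had log2 levels of 5.30 in mouse 92, 11.85 in mouse 103 and 11.67 in mouse 106. The Y-linked genes went the other way. Eif2s3y was at 10.42, 3.59 and 3.55 in the same order of mice, Uty at 9.74, 3.91 and 4.13, and Kdm5d at 9.69, 5.19 and 4.80. The background threshold lay between 5.91 and 6.10 on the 3 arrays, so that Xist was below background in mouse 92 and the Y-linked genes in mice 103 and 106. By these transcripts mouse 92 was male and mice 103 and 106 were female, although no label gives the sex.

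After the sex-linked list, neutrophil genes had the largest share of varying genes among the 26 lists. Of the 11 neutrophil genes tested, 8 varied over all genes tested and 10 when adjusted over the list alone (Fisher's exact test of the 8 against all tested genes, adjusted p = 3.09e-17 over the lists). Every tested member was lowest in mouse 92. Genes of a list are not independent replicates, so the exact tests of this paragraph describe these 3 mice and are not evidence from several animals. The granule protein gene Ngp had log2 levels of 6.88, 9.63 and 9.61 in mice 92, 103 and 106 (adjusted p = 7.90e-06, limma), a range of 6.73-fold. Lcn2, which encodes a siderophore-binding protein, was at 6.93, 9.72 and 9.45 (adjusted p = 9.71e-06, limma), a range of 6.89-fold. The calprotectin genes S100a9 (6.80, 9.18 and 8.72) and S100a8 (6.18, 8.68 and 8.13) and the lactoferrin gene Ltf (6.64, 8.51 and 8.44) were likewise lowest in mouse 92. The levels of these neutrophil genes in mouse 92, 6.18 to 6.93, were close to the background threshold of 5.91 on its array, which may limit the ranges. B cell genes varied in 3 of 13 cases, Bank1, Cd79a and Cr2 (exact test, adjusted p = 8.15e-05), and in 9 when adjusted over the list alone; all 13 were lowest in mouse 92. Cd79a, a chain of the B cell receptor, was at 7.12, 8.26 and 8.44. Among 5 erythroid genes tested, Alas2, the erythroid enzyme of haem synthesis, varied, at 8.18, 10.14 and 10.03, with 3 passing when adjusted over the list alone (Alas2, Car1 and Slc4a1), and among 15 macrophage and dendritic cell genes Lyz2 varied, at 9.36, 10.67 and 10.02, with 6 passing when adjusted over the list alone (C1qb, C1qc, Fcer1g, Itgam, Lyz1 and Lyz2). Neither of these lists passed the exact test for its share of varying genes (adjusted p = 0.107 and 0.252). No gene of the other fixed lists varied over all genes tested. Adjusted over the list alone, 3 double-positive genes (Aqp11, Cd1d1 and Rag2), 4 early progenitor genes (Dtx1, Il2ra, Lmo2 and Mef2c), 3 genes of the gamma-delta T and NK list (Ccl5, Nkg7 and Tbx21), 2 interferon-induced genes (Ifit1 and Oasl2) and 1 gene each of the PI3K-AKT-mTOR (Rheb), oncogene (Lmo2) and MHC class II (Cd74) lists passed.

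The other genes among the 20 with the smallest p-values belonged to no fixed list. The ephrin receptor gene Epha2 was at 8.96 in mouse 92, 6.49 in mouse 103 and 6.53 in mouse 106 (adjusted p = 8.69e-05, limma). The calcium channel gene Cacna1c was at 8.32, 6.13 and 8.34, and Cyb5a, which encodes cytochrome b5, at 11.55, 11.25 and 9.96. Chil3, a chitinase-like gene of myeloid cells, was at 4.91, 7.05 and 7.05, and Anxa1, an annexin gene, at 6.57, 8.40 and 8.33. Dnah8, an axonemal dynein gene, was at 9.75, 10.16 and 11.48, Ddx43 at 4.65, 6.88 and 5.38, and the pseudogene Gpr137b-ps, whose signal may be shared with its parent gene, at 5.58, 7.28 and 7.30. The small RNA genes n-R5s136, a copy of 5S ribosomal RNA, and Snord14e were at 12.41, 11.38 and 13.56 and at 9.79, 8.74 and 10.45. Mouse 92 was farthest from the mean for 29 of the 44 genes, mouse 106 for 9 and mouse 103 for 6. The count of 44 depends on a choice of degrees of freedom made after the data were examined: with the robust prior's per-gene degrees of freedom, limma called 0 genes, with 600 at an unadjusted p under 0.05. With a prior that was not robust, which needs no such choice and was set before the data were examined, limma called 30 genes, all 30 among the 44 and the 20 named genes among them. Without mouse 92, 58 genes passed, of which 14 were among the 44, and Xist, Ngp, Lcn2, Epha2, S100a9, S100a8, Alas2, Chil3, Ltf, Anxa1 and Gpr137b-ps no longer did; Cacna1c and Snord14e did not pass without mouse 103, nor Dnah8 and Cyb5a without mouse 106, where 84 genes passed, 36 of them among the 44.

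**Figure D2:**
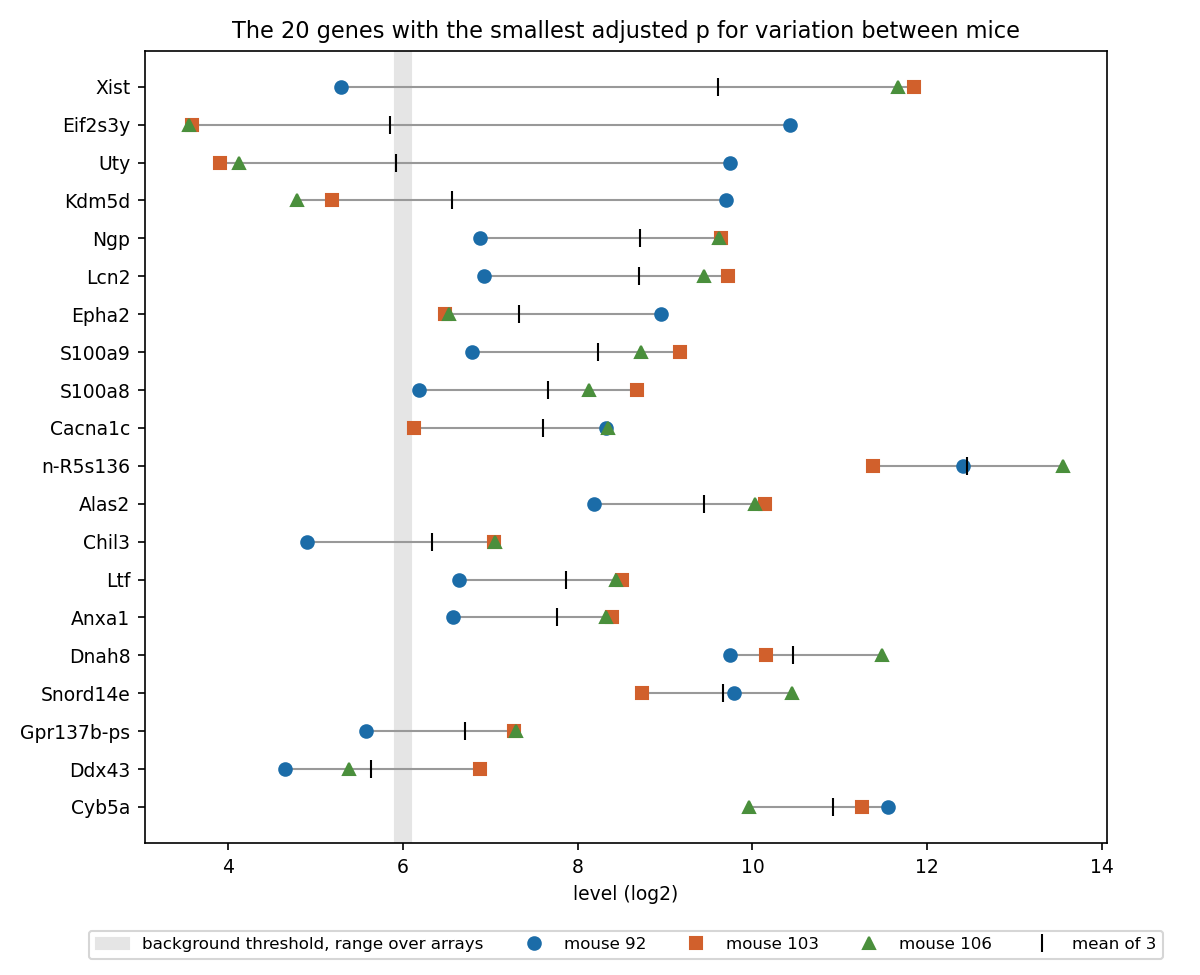
Log2 level in each mouse (symbols) and mean of the 3 mice (tick) for the 20 genes with the smallest adjusted p; the grey band spans the background thresholds of the 3 arrays, 5.91 to 6.10. Mouse 92 lies apart from mice 103 and 106 for Xist, the Y-linked genes and the neutrophil genes.

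Whether the members of a list moved together between mice was described against 10000 random lists matched on level. The SD between mice of the list mean was at or above the 99th percentile of random lists for 9 of 25 lists, where 0.25 are expected by chance. The neutrophil list had an SD of 0.91 against a median of 0.06 for random lists. Its mean lay 1.03 below the average of the mice in mouse 92 (deviation -1.03, SE over 12 genes 0.15), and 0.35 and 0.68 above it in mice 106 and 103. The B cell list deviated by -0.53 in mouse 92 (SE over 14 genes 0.06), 0.17 in mouse 106 and 0.37 in mouse 103, the erythroid list by -0.44, 0.02 and 0.42, the MHC class II list by -0.29, 0.05 and 0.24, and the macrophage and dendritic cell list by -0.23, -0.03 and 0.26. The list of gamma-delta T, NK and cytotoxic cells deviated by -0.23, 0.05 and 0.18. The early progenitor list (-0.25, 0.12 and 0.13) and the oncogene list (-0.18, 0.10 and 0.08), which share Notch1, Notch3, Lmo2, Lyl1 and Tal1, also stood apart. Interferon-induced genes deviated by 0.13 in mouse 106 and -0.13 in mouse 103.

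Several programmes stood below the 95th percentile of random lists of their level. The PI3K-AKT-mTOR list stood at the 44.3rd percentile, with deviations of 0.03, -0.05 and 0.03 in mice 92, 103 and 106, but at percentile 93.2 without mouse 92 and 0.39 without mouse 103. Housekeeping genes stood at the 46.7th percentile, T cell receptor genes at the 60.7th, glycolysis genes at the 62.7th (95.9 without mouse 92, 93.3 after quantile and 90.8 after cyclic loess normalisation) and immediate early and heat shock genes at the 14.7th. The double-positive list was 0.12 above its mean in mouse 92 and stood at percentile 94.98. It stood at 97.7 after quantile normalisation, 95.3 after centring on the median and 95.9 after cyclic loess. With mouse 103, 106 or 92 left out, it stood at 96.4, 91.1 and 16.1. The cell cycle list was 0.10 above its mean in mouse 106, at the 93.3rd percentile. The cell cycle list stood at percentile 99.9 after quantile normalisation and also after cyclic loess normalisation, at 82.5 after centring on the median and at 26.3 without mouse 106. Thymic epithelial genes deviated by -0.09, 0.14 and -0.05 (94.8th percentile) and fibroblast and endothelial genes by -0.05, 0.12 and -0.07 (85.8th percentile).

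The array identifiers in the labels share 30 of 32 leading digits for mice 92 and 106, and 9 for mouse 103 with either of them; what the digits mean is not stated. Within that pair, over members above background on all 3 arrays, 7 neutrophil genes were on average 3.39-fold higher in mouse 106 than in mouse 92 (log2 difference 1.76, SE over genes 0.31). By the same measure 9 B cell genes were 1.55-fold (0.63, SE 0.12) and 8 MHC class II genes 1.27-fold higher (0.34, SE 0.09). The difference was smaller relative to its SE over genes for 5 erythroid genes (0.61, SE 0.34) and 15 macrophage and dendritic cell genes (0.18, SE 0.10). Each side of the pair is a single mouse, so the SE measures scatter among genes and no spread between mice. Lists of other kinds also differed within the pair by the same log2 difference. Early progenitor genes (0.37, SE 0.11), gamma-delta T and NK genes (0.32, SE 0.09), oncogene list members (0.31, SE 0.07) and cell cycle genes (0.18, SE 0.04) were higher in mouse 106. T cell receptor (-0.12, SE 0.04), double-positive (-0.18, SE 0.07) and MHC class I (-0.11, SE 0.02) genes were lower there. The list deviations given above also include members below background on some arrays. Without mouse 92, the SD of the list mean was 0.24 for neutrophils, against 0.91 with it, and 0.28 for erythroid genes, against 0.43. Then 4 lists stood at or above the 99th percentile (neutrophils, macrophages and dendritic cells, erythroid cells and interferon-induced genes), whereas the B cell list stood at 98.99, the MHC class II list at 97.6, the gamma-delta T and NK list at 83.5, the oncogene list at 18.8 and the early progenitor list at 11. The interferon-induced list stood at the 87.4th percentile without mouse 106, at percentile 93.6 without mouse 103 and at percentile 98.4 after quantile normalisation.

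**Figure D3:**
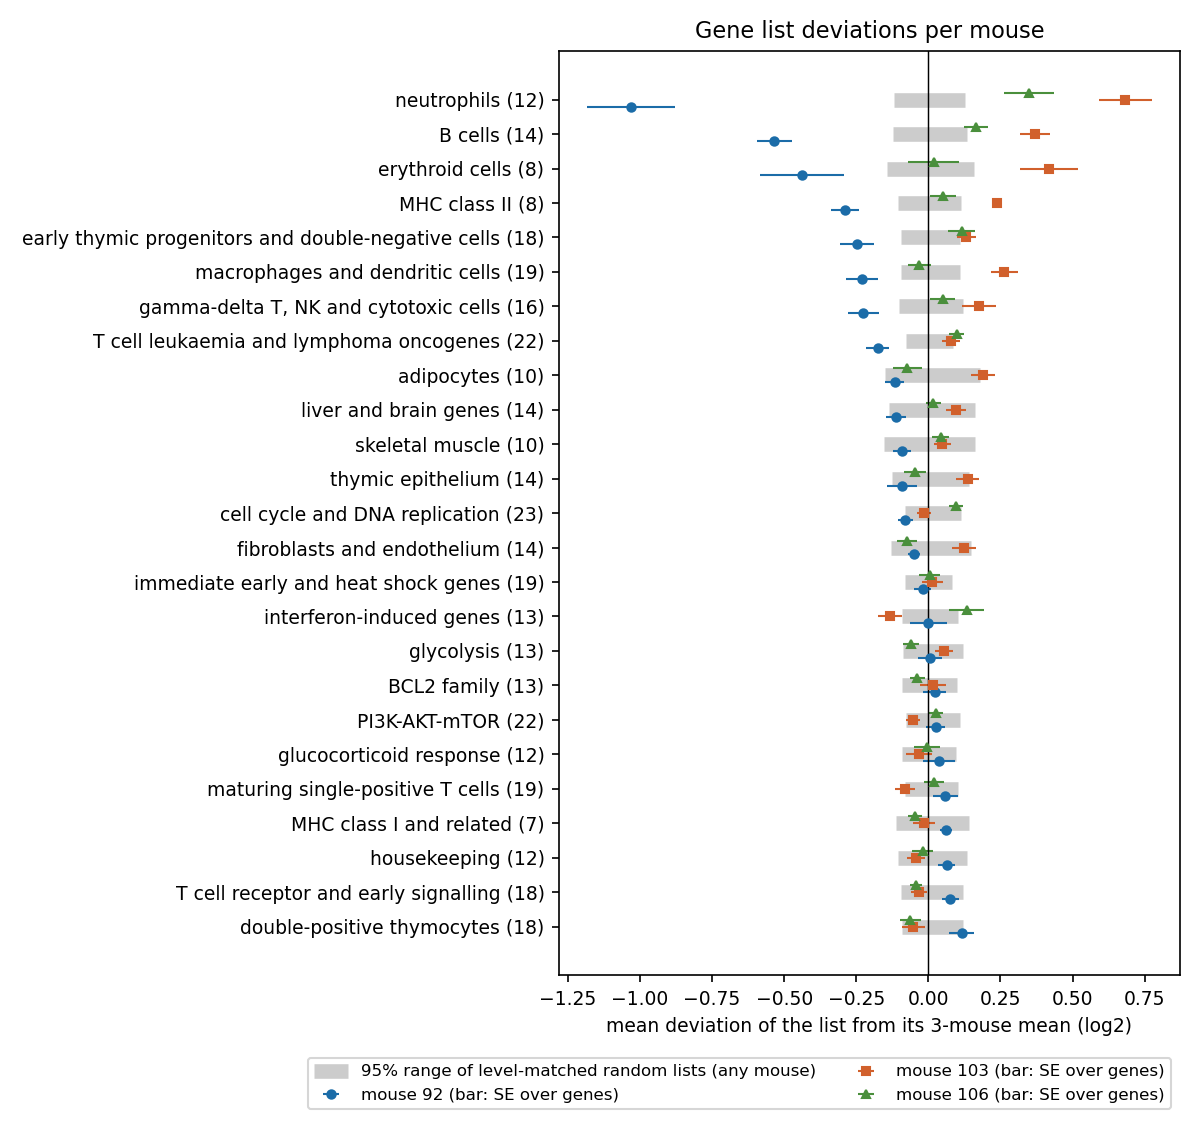
Mean deviation of each gene list (number of genes in brackets) from its 3-mouse mean, per mouse, on the log2 scale. Bars are standard errors over genes. Each grey band runs from the lowest to the highest limit of the 95% ranges of level-matched random lists in the 3 mice. A value inside a band can thus lie outside the range of its own mouse, as for the cell cycle list in mice 92 and 106. Neutrophil genes range from -1.03 in mouse 92 to 0.68 in mouse 103, while the PI3K-AKT-mTOR list stays within its band.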

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

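Cyclic loess, the per-gene prior degrees of freedom, the sex-linked list left out and the receptor genes left out of the comparison were chosen after seeing the data. The direction changed under some alternatives only for differences in the percentage of list members above background that passed the exact test in neither setting; the cause of the moves below was not tested except where the alternative itself sets it. Restricting the pairwise comparison to genes above background on all arrays, which leaves fewer genes, lowered the number differing by at least 1 on the log2 scale from 91 to 44 for mice 92 and 103, from 57 to 34 for mice 92 and 106 and from 25 to 14 for mice 103 and 106. The number of genes above background was 12454 to 12500 with a mouse left out and 9334 with the 99th percentile of the receptor genes. The number of genes varying between mice, 44, became 51 to 84 with a mouse left out (84 without mouse 106), 60 after quantile normalisation with 44 shared, 39 after cyclic loess with 38 shared, 30 with a prior that was not robust, with 30 shared, 32 without a filter on dim genes, with 31 shared, and 33 among genes above background on all arrays, with 28 shared. With the robust prior's per-gene degrees of freedom it was 0 in limma, with 600 genes at an unadjusted p under 0.05; that was the setting run at first, the change from it was made after this count was seen, and on simulated data it recovered 0 of the shifted genes. Of the 20 named varying genes, 11 no longer passed without mouse 92, where the Y-linked genes were below background and not tested, 2 without mouse 103 and 2 without mouse 106; leaving out a mouse leaves 1 degree of freedom. The lists with more members above background numbered 9 to 11, and those with fewer 2 to 2, with a mouse left out. The lists at or above the 99th percentile of shared variation, 9, numbered 4 to 8 with a mouse left out (4 without mouse 92), and 10 after cyclic loess. For single lists, 58 recomputed SDs of the list mean moved by more than the SD of random lists and 142 did not; of the recomputed list level calls, 3 were lost, 5 were gained, 181 kept direction and side of the threshold and 11 changed direction. With the 99th percentile of the receptor genes, the difference to other genes in percentage points turned to -2.37 for early progenitors, -3.07 for gamma-delta T and NK cells, -18.3 for B cells, -9.32 for erythroid cells, -3.96 for thymic epithelium and -6.82 for skeletal muscle. With the receptor genes left out of the comparison it turned to -1.21 for B cells and -3.00 for erythroid cells. With a mouse left out it ranged from -4.36 to 20.9 for neutrophils (20.9 without mouse 92, against -3.43 with all mice) and from -0.194 to 0.0364 for erythroid cells. A background from antigenomic control probes was not run, because no annotation used here names them. No paired analysis was possible because the labels give a single group. Signal over background limits the genes near the threshold, including the adipocyte, stromal and early progenitor members that passed on some arrays only.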

Other observations

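Of the tests in this part, the close-pair test over all varying genes and the test of small RNA recovery were written before their results were seen, and the other 4, cyclic loess included, after. Beyond the fixed lists, the 44 varying genes included several at their lowest level in mouse 106. Mgst2, a microsomal glutathione transferase gene, was at 9.15, 8.80 and 7.61 in mice 92, 103 and 106, and Anxa5, which encodes annexin V, at 10.53, 10.49 and 9.32, alongside Cyb5a. Trim12a, a tripartite motif gene, was at 11.02 in mouse 92 and 9.51 and 9.82 in mice 103 and 106, and Bex1 at 7.74, 6.07 and 6.30. Higher in mice 103 and 106 were Ube2l6, an interferon-inducible ubiquitin-conjugating enzyme gene (6.54, 7.87 and 7.80), the desaturase gene Scd1 (5.69, 7.07 and 6.96), Lypd1 (7.33, 8.77 and 8.48) and Ifitm6 (4.31, 6.35 and 5.75). These genes were chosen after their values were seen.

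The list means of neutrophils, B cells, erythroid cells and MHC class II were lowest in mouse 92, which also carried the Y-linked transcripts. The tables argue against a level-dependent shift between the arrays, since after cyclic loess the mean deviation of mouse 92 over the 42 members of these lists was -0.60, against -0.61 before and a 95% range of -0.06 to 0.04 for matched random lists. Neutrophil genes and macrophage and dendritic cell genes did not shift by like amounts. The members compared had a mean level over the 3 mice above the mean 99th percentile of the receptor genes. By this rule 7 neutrophil genes deviated in mouse 92 by -1.25 and 12 macrophage and dendritic cell genes by -0.27 (difference -0.98, SE over genes 0.23). In mouse 92 these neutrophil genes read only 6.18 to 6.93. The background threshold of that array was 5.91 and its 99th percentile 6.68, so background may limit the neutrophil deviation. A lower share of thymocytes in mice 103 and 106 would raise other cell types alike, but gives equal log2 shifts only for genes that thymocytes do not transcribe. That was not measured, and genes are not independent replicates, so the comparison does not decide whether a lower share of thymocytes was the cause. Stromal genes lay too near background to decide this; the macrophage comparison was chosen after all list values had been seen. The neutrophil, B cell, erythroid, macrophage and dendritic cell, and gamma-delta T and NK lists were grouped as blood-derived, an origin not checked here for each cell type. Of their 56 members above background on at least 1 array, 85.7% were lowest in mouse 92. These lists had been seen to be low there, so the share does not bear on whether the sample held fewer blood-derived cells. That question stays open. Stromal members were lowest in mouse 92 in 33.3% of 21 cases and all tested genes in 35.1%. But 16 of 19 genes of the oncogene list and 12 of 16 early progenitor genes were also lowest there. So were 6 of 8 skeletal muscle genes, 3 of 4 adipocyte genes and 4 of 4 liver and brain genes. Random lists matched on level to the skeletal muscle, adipocyte and liver and brain lists averaged -0.05, -0.06 and -0.06 in mouse 92. The lists themselves averaged -0.09, -0.12 and -0.11 there, and the share of 35.1% is not matched on level. By its sex-linked transcripts mouse 92 was the only male, so its differences from mice 103 and 106 cannot be told apart from sex. Sex and age as causes stay open and untested.

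A mixed FVB and C57BL6 background may leave chromosome segments of different origin in each mouse, in which case varying genes would lie close together. Among 79 genes with an unadjusted p under 0.001, sex-linked genes left out, 10 pairs with different symbol stems lay within 10 tested genes of each other, against a mean of 4.53 in random sets of genes (one-sided permutation p = 0.0186). With every member of a fixed list left out, 58 genes gave 6 pairs against a mean of 2.42 (permutation p = 0.0372). The pairs are not independent, since Anxa1, Gda and 1110059E24Rik form 3 of these 6, and Camp with Ngp, among the 10, are both neutrophil genes of the cathelicidin family, which the symbol stems do not show. Some pairs, such as Ero1b with Gpr137b-ps, varied in opposite directions over the mice. Clusters of genes used by the same cell type stay open for part of the excess, and genotypes were not analysed here.

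Small RNA genes were over-represented among the varying genes, with 5 of 181 (Mir142, n-R5s136, Snord14e, Snord22 and Snord47; two-sided Fisher's exact test, p = 3.10e-04), and a difference in small RNA recovery between the extracts could produce this. A difference common to the whole class would shift the class mean between mice. The SD of that mean between mice stood at the 32.9th percentile of level-matched random lists, with deviations of -0.02, -0.01 and 0.03 in mice 92, 103 and 106. Among the varying small RNA genes, Mir142, n-R5s136, Snord14e and Snord22 were highest in mouse 106 and Snord47 in mouse 92. The class mean cannot exclude a recovery difference that touches only some small RNAs, which stays open. A noisier measurement of short transcripts also stays open, and their median SD was 0.16 against 0.13 for all tested genes.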
